A study of Oryctolagus cuniculus with 3 samples.

How the data were processed

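Back skin was taken from 3 Rex rabbits, full siblings of 1 litter, at 42 days of age, when the first moult takes place. Rex is a domestic breed with short plush fur. 1 animal had black fur, 1 had white fur and 1 had chinchilla fur, and each gave 1 RNA library. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was enriched on oligo(dT) beads and fragmented, and double-stranded cDNA was made into Illumina libraries. Whether the libraries kept the strand of the RNA is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be separated.

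Per the file headers, the authors deposited for each library a list of Ensembl rabbit protein identifiers with the number of uniquely assigned reads, a length, the covered share of that length and an RPKM value. The deposited read counts are whole numbers of at least 1, and their sum equals the total in the header of each list. An identifier missing from a list was taken as 0 reads. The deposited percentages of coverage give the part of each sequence that reads touched. All lengths are multiples of 3, so they are coding lengths without untranslated regions, and the entries are called coding sequences here. The deposited RPKM values, read numbers scaled to coding length and library total, were recomputed from the counts, and the largest relative difference was 1.6e-14. The library total behind them is therefore the number of reads assigned to coding sequences, and not of all sequenced reads. The aligner, the counting program, the genome build and the annotation release are not given in the sources used here. Because only unique reads were counted, sequences with a near-identical copy in the genome can be undercounted.

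None of the identifiers could be paired with a gene symbol. The deposited lists carry no symbols, and 0 of the 38822 entries of the RefSeq gene table used here hold an Ensembl identifier. The 23 gene lists fixed before the data were examined, which cover pigment cells, hair follicle, epidermis and other cell types of skin, were therefore not evaluated. The rule fixed for named genes asked for symbols. In its place, the 2 coding sequences with the largest and the 2 with the smallest log2 difference of each comparison are printed by identifier, and the most abundant ones are described by their length. No coordinates are given, since no genome build is named.

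With 1 animal per coat colour there is no replicate, so no test across animals was possible and no p-value is given. Differences describe these 3 libraries. They were computed as log2(RPKM + 1) of one library minus log2(RPKM + 1) of the other, a scale that understates the fold of low coding sequences. A coding sequence was counted as higher or lower at a difference of at least 1 (2-fold) with at least 1 RPKM in the higher library. Ratios of RPKM were given an exact 95% interval, from the Clopper-Pearson interval of the conditional binomial share of the reads of both libraries. Counts of intervals beyond 2-fold cover all compared coding sequences, on ratios without a pseudocount, so they are not a subset of the 2-fold calls. Reads without molecular identifiers are not independent molecules, and these intervals cover counting error only. Chance from counting alone was taken from 100 Poisson draws of the 3 libraries from their common profile. In 15558 simulated coding sequences per comparison, 200 of them changed 4-fold, 96.0% of the changed ones were recovered for black against white, 96.5% for chinchilla against white and 99.0% for black against chinchilla. The unchanged ones gave 8, 9 and 5 calls in the same order, and the intervals held the true ratio in 95.5%, 95.9% and 95.2% of coding sequences with at least 10 reads.

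Trends with coding length were described in quintiles of coding length among coding sequences with a mean of at least 5 RPKM, and were removed in an alternative by a lowess curve (fraction 0.3) on log2 length. In simulated libraries with an added length trend, this curve brought the gap between longest and shortest quintile from 0.55 to 0.00 (log2) for black against white. Covered shares were compared among coding sequences with 50 to 200 reads in both libraries and read numbers within 25% of each other. The alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no RPKM floor and a floor of 5, 3 other scalings, a 4-fold threshold, counting intervals beyond 2-fold, and a minimum of 10 reads. Removal of the length trend was added after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.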

Results

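The data were RNA-seq libraries of back skin from 3 full-sibling Rex rabbits with black, white or chinchilla fur, 1 library per coat colour, made to find genes that take part in fur colour. Chinchilla fur is a banded grey coat. The black library held 16.2 M reads assigned to coding sequences (M for mega), the white library 14.8 M reads and the chinchilla library 15 M reads. Reads were found for 14795 coding sequences in black, 14584 in white and 14753 in chinchilla skin, and 13893 of the 15558 seen in any library had reads in all 3. Any coding sequence with at least 1 read counted as having reads. Behind a count of 0, an expected number of up to 3 reads was taken as possible. At the median coding length of 1275 bases, 3 reads are 0.145 RPKM in black, 0.159 RPKM in white and 0.157 RPKM in chinchilla skin. The median coding sequence with reads had 307 reads in the black library, 274 in the white and 278 in the chinchilla library. Of the coding sequences with reads in both other libraries, 254 had none in black, 319 had none in white and 215 had none in chinchilla skin.

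A small set of coding sequences took a sizeable part of the reads assigned to coding sequences in all 3 skins. The 10 with most reads took 10.4% of the reads in black, 13.2% in white and 12% in chinchilla skin, and the 50 with most reads took 19.1%, 23.3% and 22.8%. A coding sequence of 1389 bases was first or second by RPKM in each library, with 10356 RPKM in black, 12003 RPKM in white and 13772 RPKM in chinchilla skin. Others near the top differed more between the animals. One of 1707 bases had 5650 RPKM in black, 8905 RPKM in white and 15600.1 RPKM in chinchilla skin, where it ranked first. One of 1890 bases had 3806 RPKM in black, 6019.9 RPKM in white and 9858 RPKM in chinchilla skin. One of 300 bases had 3120.3 RPKM in black, 5275 RPKM in white and 10423 RPKM in chinchilla skin. In the other direction, one of 4149 bases had 7865 RPKM in black, 6699.5 RPKM in white and 3465 RPKM in chinchilla skin, and one of 1350 bases had 8475 RPKM, 10880.3 RPKM and 5745 RPKM in the same order. The gene names behind these sequences are not known here.

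Black against white skin compares skin under pigmented fur with skin under white fur. Of 12401 coding sequences with at least 1 RPKM in either library, 700 were at least 2-fold higher and 207 at least 2-fold lower in black skin, together 7.31%. At 4-fold, 110 were higher and 12 lower, and at 8-fold, 56 were higher and 2 lower. ENSOCUP00000003355, a coding sequence of 411 bases, had the largest log2 difference (7.42), but with a pseudocount of 0.1 in place of 1 it came after 3 others, ENSOCUP00000017571 among them (8.29 against 8.33). It had 2258 reads (338 RPKM) in black and 6 reads (0.985 RPKM) in white skin, a 344-fold ratio (95% interval 158 to 937). ENSOCUP00000017571, of 5838 bases (log2 difference 7.33, or 6.71 with the length trend removed), had 27301 reads (288 RPKM) in black and 69 reads (0.797 RPKM) in white skin, a 361-fold ratio (285 to 464). The lowest log2 difference was that of ENSOCUP00000020789, of 1911 bases, with 10 reads (0.322 RPKM) against 1170 reads (41.3 RPKM) in white, where it was 128-fold higher (69.4 to 268). Its reads covered 52.2% of the coding sequence in white skin in spite of their number. ENSOCUP00000022437, of 774 bases, had 2 reads (0.159 RPKM) in black and 95 reads (8.28 RPKM) in white, where it was 52.0-fold higher (14.0 to 436). Reads covered 72.7% of it in white skin.

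The differences between black and white skin were spread unevenly over abundance and coding length. Among 3807 coding sequences of 5 to 20 RPKM, 328 were higher and 58 lower in black skin. Among 1236 of 100 to 1000 RPKM the numbers were 18 and 20, and among 119 of at least 1000 RPKM they were 0 and 4. The shortest quintile, of up to 696 bases, had a median log2 difference of -0.29, with 48 coding sequences higher and 65 lower in black. The longest quintile, from 2373 bases, had a median of 0.38, with 244 higher and 6 lower. At matched read numbers, the longest coding sequences were also covered more fully in black than in white skin, by a median of 4.5 percentage points. Counting alone gave a mean of 10.1 coding sequences 2-fold apart in the simulated libraries, against 907 observed. Over all compared coding sequences, called or not, the counting interval lay beyond 2-fold for 577 higher and 112 lower in black. These differences have no replicate check.

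**Figure D1:**
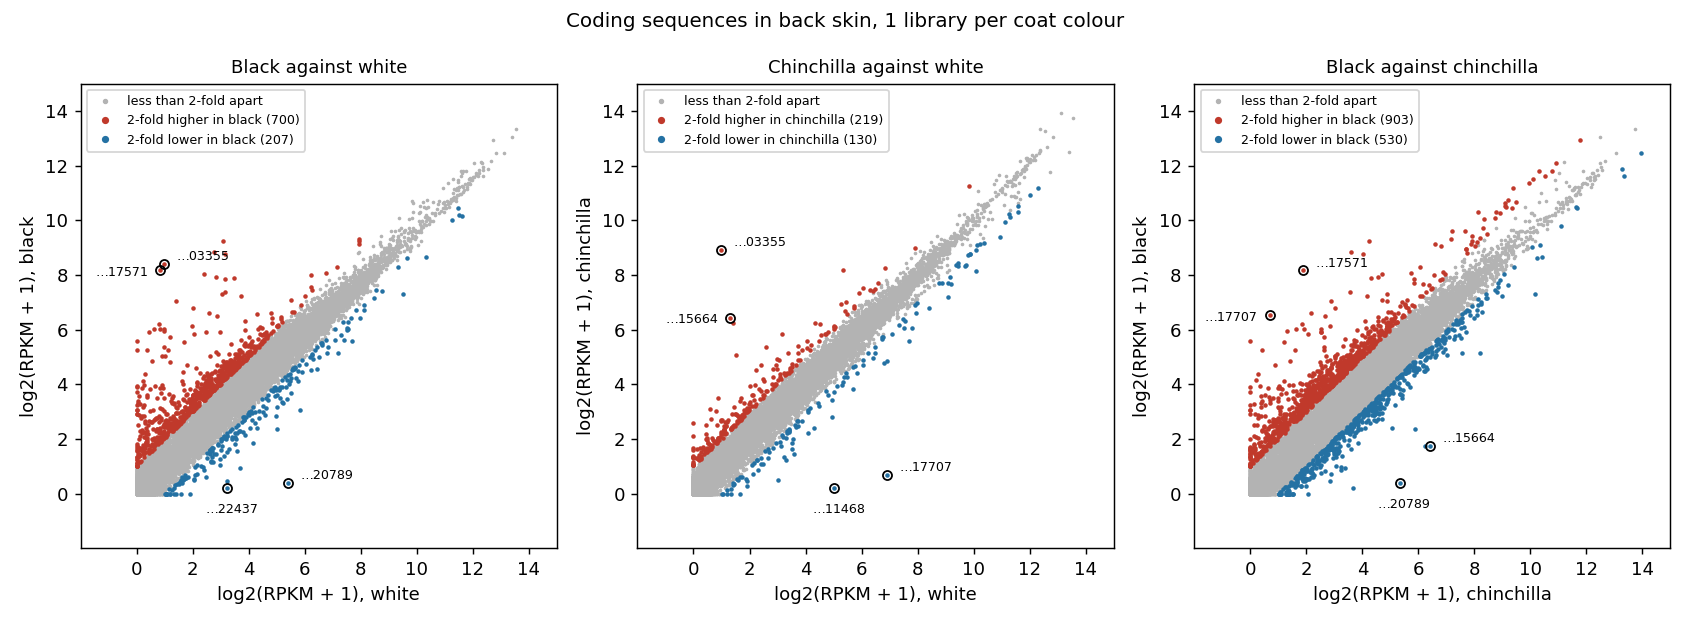
Expression of coding sequences in each pair of libraries, on log2(RPKM + 1) axes with 1 point per coding sequence. Red and blue points were at least 2-fold higher or lower in the library on the vertical axis (700 and 207 for black against white, 219 and 130 for chinchilla against white, 903 and 530 for black against chinchilla), and circles mark the 2 largest differences each way by the last 5 digits of the identifier.

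Chinchilla and white skin had the fewest coding sequences 2-fold apart of the 3 pairs. Of 12310 coding sequences, 219 were at least 2-fold higher and 130 lower in chinchilla skin, together 2.84%, and 16 and 9 passed 4-fold. The balance between higher and lower depended on the pseudocount and the floor: with 5 in place of 1, 53 were higher and 62 lower. With a floor of 5 RPKM, 134 were higher and 103 lower. ENSOCUP00000003355 again had the largest difference, with 2973 reads (482 RPKM) in chinchilla against 6 reads in white skin, a 489.8-fold ratio (225 to 1336). ENSOCUP00000015664, of 366 bases, had 466 reads (84.9 RPKM) in chinchilla, 8 reads (1.47 RPKM) in white and 14 reads (2.36 RPKM) in black skin, and was 57.6-fold higher in chinchilla than in white (29.0 to 134). ENSOCUP00000017707, of 1203 bases, was nearly missing from chinchilla skin, with 11 reads (0.610 RPKM) against 2133 reads (119.6 RPKM) in white, where it was 196-fold higher (109 to 394). Reads covered 63.6% of it in white skin. ENSOCUP00000011468, of 438 bases, had 1 read (0.152 RPKM) in chinchilla and 206 reads (31.7 RPKM) in white, a ratio of 208 in favour of white whose interval ran from 37.0 to 8270.1. Reads covered 82.2% of it in white skin.

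By abundance, the lower calls in chinchilla skin lay more among abundant coding sequences than the higher calls. Of 123 coding sequences with a mean of at least 1000 RPKM, 8 were lower and 1 was higher in chinchilla than in white, although the median over all 123 was slightly higher in chinchilla (log2 difference 0.10). Of 1319 between 100 and 1000 RPKM, 29 were lower and 10 higher, with a median of -0.02. Of 2520 below 5 RPKM, 118 were higher and 34 lower. The median difference moved little with coding length, from 0.02 in the shortest to 0.06 in the longest quintile (log2). Counting alone gave a mean of 11.1 coding sequences 2-fold apart against 349 observed. Over all compared coding sequences, called or not, the counting interval lay beyond 2-fold for 119 higher and 76 lower in chinchilla, a total of 195.

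Black and chinchilla skin, the skins under the coloured coats, had the most coding sequences 2-fold apart. Of 12516 coding sequences, 903 were at least 2-fold higher and 530 lower in black skin, together 11.4%, and 112 and 16 passed 4-fold. ENSOCUP00000017571 was 106-fold higher in black (93.6 to 121), with 237 reads (2.71 RPKM) in chinchilla skin. ENSOCUP00000017707 had 1782 reads (91.2 RPKM) in black and was 149.6-fold higher there than in chinchilla (83.4 to 300.3). ENSOCUP00000020789 had 1123 reads (39.2 RPKM) in chinchilla, where it was 122-fold higher than in black (65.9 to 254), and ENSOCUP00000015664 was 36-fold higher in chinchilla than in black (21.3 to 66.4). Of 113 coding sequences with a mean of at least 1000 RPKM, 13 were higher and 6 lower in black skin by 2-fold, while the median over all 113 was lower in black (log2 difference -0.51). The median log2 difference ran from -0.31 in the shortest to 0.34 in the longest quintile of coding length, where black skin was also better covered at matched read numbers, by 4.15 percentage points. Counting alone gave a mean of 10.1 coding sequences 2-fold apart, against 1433 observed. Over all compared coding sequences, called or not, the counting interval lay beyond 2-fold for 737 higher and 293 lower in black.

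**Figure D2:**
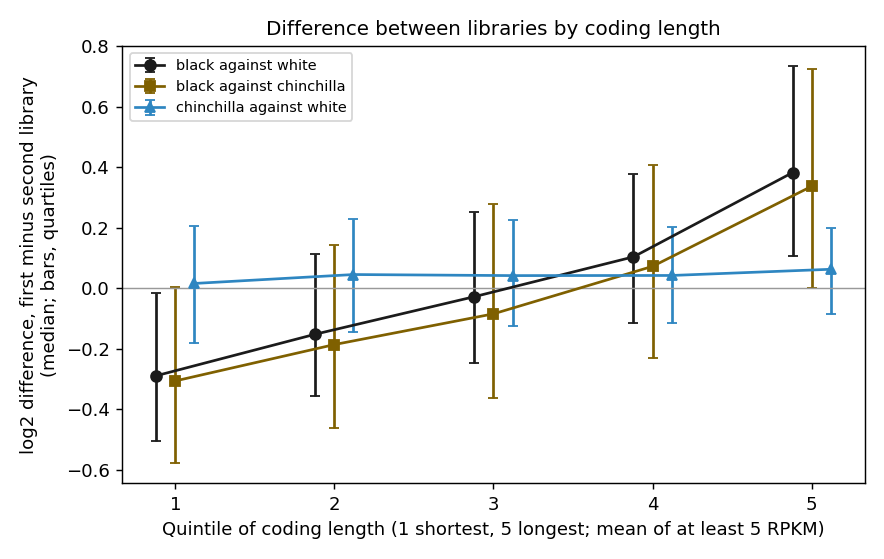
Median log2 difference (points) and quartiles over coding sequences (bars) in each quintile of coding length, for coding sequences with a mean of at least 5 RPKM. Black against white runs from -0.29 to 0.38 and black against chinchilla from -0.31 to 0.34, while chinchilla against white stays between 0.02 and 0.06.

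The black library stood apart from both others most often. In black skin, 527 coding sequences were at least 2-fold higher than in both other skins and 103 were lower than in both. The 527 had a median length of 2223 bases and a median of 14.2 RPKM in black against 3.67 in white and 3.81 in chinchilla skin, and 78 of them were at least 4-fold higher than in both. They took 4.60% of the reads in black, 1.31% in white and 1.26% in chinchilla skin. The 103 lower ones had a median length of 684 bases. With the length trend removed, the higher and lower sets of black skin numbered 419 and 77. The chinchilla library was higher than both others in 101 coding sequences and lower in 74. That balance depended on the processing. It was 72 and 91 without the length trend, 85 and 86 when scaled by the median ratio between libraries, and 30 and 43 with a pseudocount of 5. The other alternatives kept more higher than lower ones. The 74 were abundant, with medians of 87.5 RPKM in black, 88.2 in white and 29.6 in chinchilla skin, and 34 of them had at least 100 RPKM in both other libraries. They took 2.81% of the reads in black, 2.30% in white and 0.932% in chinchilla skin. Each set shares 1 library between both comparisons, which by itself makes them overlap. Independent lists of the same sizes would share 51.4 coding sequences for the higher and 7.48 for the lower set of black skin, and 9.50 and 7.77 for those of chinchilla skin. Simulated libraries that differed by counting alone gave means of 0.76 and 0.87 for black and 0.79 and 1.09 for chinchilla skin. With 1 library per coat colour, the part of each overlap that comes from sharing the library is not known.

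White skin, compared with both coloured ones, had the fewest such coding sequences. 42 were lower in white than in both black and chinchilla skin, and 29 were higher in white than in both. These counts depended on the settings. With a pseudocount of 0.1 they were 126 and 62, with 5 they were 11 and 7, and a floor of 5 RPKM left 26 and 22. The 42 had medians of 29.4 RPKM in black, 6.07 in chinchilla and 1.28 in white skin. 7 of them were at least 4-fold lower in white than in both, and ENSOCUP00000003355 was the single one with at least 100 RPKM in both coloured skins. The 29 had medians of 9.59 RPKM in white, 2.95 in black and 2.56 in chinchilla skin, and 1 was at least 4-fold higher than in both. These sets share the white library between both comparisons. Independent lists of the same sizes would share 8.68 coding sequences for the lower set and 2.22 for the higher set, and simulated libraries that differed by counting alone gave means of 1.1 and 0.71. A single white library cannot be split, so part of the excess may come from sharing it. The differences of black and of chinchilla against white had a correlation of 0.11 across 11533 coding sequences with at least 1 RPKM in every library. These coding sequences are not independent replicates. Simulated libraries gave 0.51, a level that comes from sharing the white library when all 3 differ by counting alone. The measured differences held more than counting, and their spread was unequal. Over all compared coding sequences the standard deviation was 0.62 (log2) for black against white and 0.41 for chinchilla against white. The measured and simulated correlations can therefore not be ranked. The covariance of the measured differences was 0.023, against 0.008 in simulation, a difference of 0.014. Any variation of the single white library beyond counting enters both differences and raises the covariance, so the source of this excess cannot be told.

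**Figure D3:**
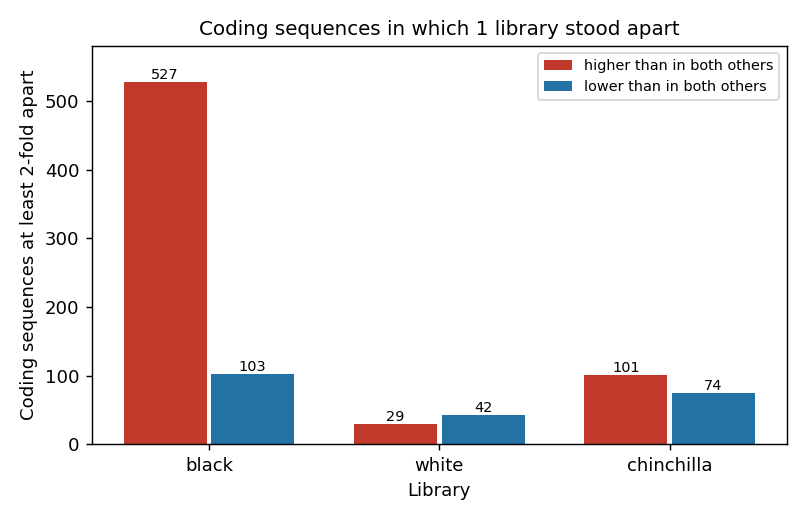
Number of coding sequences in which 1 library was at least 2-fold higher (red) or lower (blue) than both others. Black skin has 527 and 103, white skin 29 and 42, and chinchilla skin 101 and 74.

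At matched read numbers, the covered share of the longest coding sequences was higher in the black library than in both others. In the longest quintile, from 2334 bases, 98 coding sequences had matched reads in black and white skin. Their median covered share was 84.8% in black and 80.2% in white, with a median difference of 4.5 percentage points (95% bootstrap interval over coding sequences 2.91 to 6.03), and 77.6% of them were better covered in black. For 116 coding sequences matched between black and chinchilla skin, the median covered shares lay closer, at 82.7% in black and 80.3% in chinchilla. Of these, 70.7% were better covered in black, and the median difference was 4.15 points (1.6 to 5.73). Between chinchilla and white skin it was -0.29 points over 205 coding sequences (-1.1 to 0.65). In the shortest quintile, of up to 684 bases, the difference between black and white was -0.2 points over 260 coding sequences.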

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

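The order of the comparisons was the same under the alternatives run for all 3: black against chinchilla had the most coding sequences 2-fold apart and chinchilla against white the fewest. With a pseudocount of 0.1, the counts were 1457 for black against white, 730 for chinchilla against white and 2057 for black against chinchilla, and with 5 they were 328, 115 and 568. Chinchilla against white then held 53 higher and 62 lower ones, where the main setting had 219 and 130. Coding sequences in which 1 library stood apart numbered 876 in all, 1506 with a pseudocount of 0.1 and 333 with 5. With 0.1, black was lower in 193, white higher in 62 and lower in 126, and chinchilla higher in 223 and lower in 136. With 5, black was higher in 200 and lower in 42, white higher in 7 and lower in 11, and chinchilla higher in 30 and lower in 43. By construction, a higher pseudocount shrinks the differences of low coding sequences, and depth limits the same ones. A floor of 5 RPKM left 26 lower in white and 67 higher in chinchilla than in both others, and 134 higher and 103 lower for chinchilla against white. A 4-fold threshold left 122, 25 and 128 in the order of the comparisons above. Counting intervals beyond 2-fold, taken over all compared coding sequences, numbered 195 for chinchilla against white. The 3 other scalings, the minimum of 10 reads and, added after seeing the data, removal of the length trend moved no count by over 1.5 times. Without the length trend, 733, 343 and 1232 coding sequences were 2-fold apart. Against both others, black was then higher in 419 and lower in 77, and white higher in 22 and lower in 43. Chinchilla was higher in 72 and lower in 91, where the main setting had 101 and 74, so this balance turned. Scaling by the median ratio between libraries gave 85 and 86 for chinchilla. Leaving out the RPKM floor changed nothing, since the pseudocount of 1 already sets it. Of 36 alternative values for the printed identifiers, 0 changed sign, the smallest was 2.83 (log2, in size), and 8 shifted by more than the counting interval reaches from the ratio on that side, 6 with a pseudocount of 0.1 and 2 without the length trend. ENSOCUP00000017571 went from 7.33 to 6.71 for black against white without the length trend, over 1.5-fold, and with a pseudocount of 0.1 it reached 8.33, above ENSOCUP00000003355 (8.29), which has the largest difference in the main setting. The gene list alternatives were not run, since no symbols were at hand. No library could be left out, with 1 per coat colour. No paired analysis was possible because each coat colour has 1 library: the 3 siblings form a single block, which leaves no residual degrees of freedom.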

Other observations

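The tests in this part that were chosen after the result had been seen are the test of scaling for the length trend, both tests of the set raised in black skin, and the tests of near-missing coding sequences other than the counting simulation and the covered share of the residual reads. Near-missing coding sequences occurred in each of the 3 skins. Of those with at least 10 RPKM in 2 libraries, 4 were at least 16-fold lower in the third: ENSOCUP00000020789 in black, ENSOCUP00000003355 in white, and ENSOCUP00000017707 and ENSOCUP00000011468 in chinchilla skin. This fold was a ratio of RPKM without a pseudocount, with counts under 3 reads set to 3. On the log2(RPKM + 1) scale, ENSOCUP00000011468 was 3.95 lower in chinchilla than in black skin, just under 16-fold. A set of 38 coding sequences was at least 8-fold higher in black skin than in both others, against 0 for white and 2 for chinchilla skin. This set had a median of 60.2 RPKM in black, 0.80 in white and 2.65 in chinchilla skin, and took 0.809% of the reads in black, 0.0169% in white and 0.0348% in chinchilla skin. It overlaps the 42 coding sequences lower in white than in both coloured skins, since ENSOCUP00000017571 belongs to both sets. How many others they share was not counted.

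The first pattern is the rise of the black-minus-white and black-minus-chinchilla differences with coding length, with gaps between longest and shortest quintile of 0.67 and 0.64 (log2), against 0.05 for chinchilla minus white. Scaling by a total that a few abundant coding sequences dominate is argued against by the smaller gap itself (0.64), since a total shifts all coding sequences of a library by 1 constant and gives no gap between quintiles. A trend of abundance is argued against, since the smaller gap was 0.55 within 20 to 100 RPKM. Unequal coverage along transcripts is a candidate explanation: long coding sequences at matched read numbers were better covered in black skin, by 4.15 percentage points or more against both others. From the shortest to the second longest quintile, the coverage difference was -0.2, -0.11, 0.27 and 0.94 points against white. Against chinchilla it was 0, -0.095, 0 and 0.25 points, with intervals that included 0. The log2 difference of black minus chinchilla still rose through these quintiles, from -0.31 to 0.07, without a matching difference in coverage. Median covered shares there were above 92%, which leaves less room for a difference. Whether RNA integrity, fragment size or the animal itself lies behind the rise with coding length stays open, since each coat colour has 1 library.

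The second pattern is the set of 38 raised in black skin. The fitted length trend reached at most 0.90 (log2) at their lengths, and 8-fold is 3, so the fitted trend was too small to be the whole of the difference. The gaps between quintiles already put such a curve far below 3, so this comparison could hardly have come out otherwise. With the trend removed, 32 of the 38 stayed 8-fold higher. That share (0.84) was the test set first and fell short of its preset bound of 0.9. The fitted trend was used in its place after the share was seen. A source of RNA present in unequal amounts in the 3 skins, such as another tissue layer in the piece of skin, would move the set together between chinchilla and white as well. Of 32 members with at least 10 reads in those 2 libraries, 26 were higher in chinchilla, a share of 0.8125, where random lists matched on abundance had a median of 0.594 and at most 2.5% of them passed 0.75. A single source would also give the members a common ratio. Over the 30 of them with reads in both libraries, the log2 ratio of chinchilla to white had a median of 1.01 and quartiles of 0.30 and 1.90, with 4 members at 4-fold or more. The spread that counting alone gives at these low read numbers was not simulated, so the quartiles do not decide. A shared source stays undecided, as does a change tied to black fur, with 1 animal per colour and no member named.

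The third pattern is the 4 near-missing coding sequences. Counting noise is argued against, with a mean of 0 in 100 simulated sets. Loss of a cell type stays open, since the number per library, at most 2, is the pattern itself and decides nothing. Reads from a related sequence that pile up on a shared part stay open too: the covered share of the residual reads, among coding sequences of similar read number and length, lay at percentiles 73.0 for ENSOCUP00000020789, 14.3 for ENSOCUP00000017707 and 6.35 for ENSOCUP00000003355, and the 58.8 of ENSOCUP00000011468 rests on 1 read and carries no information, so the median of 36.5 over all 4 does not decide. The near-absence of ENSOCUP00000003355 from white skin may belong to fur colour or to that 1 animal, which cannot be told apart with 1 animal per colour and with 3 of the 4 near-absences in the coloured skins. The coverage of ENSOCUP00000020789 and ENSOCUP00000017707 was partial in white skin (52.2% and 63.6%). Coding sequences of similar read number and length had medians of 99.25% and 99.68% there. A low percentile of residual coverage, as for ENSOCUP00000017707, can thus arise without a pile-up. ENSOCUP00000011468 was covered to 82.2% in white skin, where like coding sequences had a median of 98.4%. ENSOCUP00000003355 was covered to 97.6% in chinchilla skin, against a median of 99.7%. A part that unique reads miss in all 3 libraries would not by itself lower 1 of them. Whether all 3 libraries miss the same part was not tested, so the bearing of partial coverage on the near-absence is not known. Partial coverage was tested as an explanation after the values were seen. That test was dropped on the assumption that all 3 libraries miss the same part.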
